A study of Mus musculus with 4 samples.

How the data were processed

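The samples were primary cardiac fibroblasts isolated from C57BL/6J wild-type mice aged 12 weeks. They were grown to 80% confluency and received vehicle or 10 ng/ml TGFbeta, a growth factor that turns fibroblasts into contractile, matrix-producing myofibroblasts. Cells took up 4-thiouridine, a uridine analogue that crosslinks to bound protein, at 20 and 4 h before exposure to 368 nm light at 200000 uJ per square centimetre. The labels give 2 libraries per treatment, and 4 libraries in all were used. The study design describes RNA eluted from HuR, an RNA-binding protein encoded by Elavl1, after photoactivatable crosslinking and immunoprecipitation (PAR-CLIP). The sample labels instead describe total RNA taken up in Trizol, of which 1 ug entered a TruSeq RNA library. The labels do not settle which of these the libraries hold. No input or control-antibody library was analysed here, so the level of a transcript on HuR cannot be separated from its abundance in the cell.

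Per the file headers, the deposited values are TPM, a transcript abundance scaled to a fixed total per library, per gene, computed by the authors as 1 value for each of 33641 gene symbols in each library. The TPM total was checked to be 1000000 in every library. Aligner, quantifier, genome build and annotation are not given in the sources used here. TPM keeps no record of read numbers, so the depth of each library is unknown and no counting interval is given. Positions come from GENCODE M21 (GRCm38), matched here by gene symbol: 32159 symbols matched directly, 283 through an older symbol and 1199 not at all.

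Levels were compared as log2(TPM + 1) for the 15815 genes with a mean TPM of at least 1 over all 4 libraries. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, with treatment as the only term and Benjamini-Hochberg adjustment over all tested genes. Genes with an adjusted p under 0.05 were called. A log2 change is the TGFbeta mean minus the vehicle mean of log2(TPM + 1), with the standard error (SE) of the limma fit. Mean TPM is given with its SD over 2 libraries, and fold values are ratios of mean TPM. An exact permutation test of 1 gene has 6 arrangements of the 4 libraries and a smallest p of 0.333, so it was not used. As a description without a variance model, genes were counted whose TGFbeta libraries both lay on 1 side of both vehicle libraries with at least a 2-fold change. The labels do not say whether replicates were separate cultures or separate animals. All p-values therefore measure only the spread between these samples.

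The 40 gene lists, the rule for naming genes, the limma and list tests with their thresholds and 15 alternatives were fixed before the data were examined. A further 5 lists, both tests on the interferon genes, the test that left out abundant genes and 1 alternative were chosen later. The rule named, per direction, the 12 called genes with the largest log2 change, a mean TPM of at least 5 and separated libraries, without symbols that are only clone or model names. It also named 13 fixed genes, and the 3 members of each list with the largest absolute change. Some genes that the rule names are not reported here. List members named beyond these 3 were chosen after their values were seen. The 40 lists cover matrix, contractile, signalling, stress, metabolic and RNA-binding genes and markers of other cell types; lists with at least 5 tested members were tested, 34 in all. The set test was camera (limma) with a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the 34 lists, which compares a list with all other tested genes. It was repeated with a correlation estimated from each list and with fry, which asks whether a list's genes move, on balance, 1 way. With an estimated correlation, camera also relies on the few degrees of freedom that 4 libraries leave, so it could hardly call a list. The resident fibroblast list had an estimated correlation of 0.00562, under the preset 0.01. Its camera p still went from 0.000557 to 0.0695. Other lists had estimated correlations well above the preset, such as 0.443 for interferon genes and 0.752 for mitochondrially encoded genes. For these, correlation between genes may also have ended the call. For each list, called members were also counted with p adjusted over the list alone.

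The alternatives were pseudocounts of 0.1 and 5, every gene above 0, a mean TPM of at least 5, quantile normalization, median scaling, eBayes without a trend or robust, the replicate number as a block, each library left out in turn, and the estimated correlation and fry for lists. With 1 library left out, the lone library of its group was assumed to vary like the other group. A further alternative, protein-coding genes without identical twins, was chosen after seeing the data. The procedure was tested on simulated data of the same size, in which 100 genes were changed per effect size. It recovered 16% of changes of 1 log2 unit and 86% of changes of 2 log2 units. Among 112 calls in that simulation 10 were false, and it made 0 limma calls when no gene was changed. The simulated spreads were drawn from limma's own fit, with independent normal errors and no shift shared within a library. These rates therefore hold only where that model does. Recovery also depends on the number of changed genes, which was smaller than the number called in the real data. Figures and tables used Python 3.11.15.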

Results

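RNA levels were measured by sequencing in 4 libraries of primary mouse cardiac fibroblasts, 2 given vehicle and 2 given 10 ng/ml TGFbeta. Read depth was unknown, because each library was given as TPM with a fixed total. Between 20945 and 21671 genes per library lay above 0. The 100 most abundant genes took 23.1% and 23.9% of all TPM in the vehicle libraries and 29.5% and 26.7% in the TGFbeta libraries. A trio of pseudogene entries with identical values took 6.50% in TGFbeta 1 and 2.01% to 2.92% in the other libraries. Across the 15815 tested genes, which are not independent replicates, Pearson r of log2(TPM + 1) was 0.980 between the vehicle libraries and 0.976 between the TGFbeta libraries. It lay between 0.956 and 0.965 for pairs of libraries from different treatments. The share of tested genes that differed over 2-fold was 2.30% within vehicle, 3.17% within TGFbeta and 6.82% to 8.47% between treatments.

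The comparison asked which transcripts differ in level between TGFbeta and vehicle, with Wisp1 as the gene named in the study title. With TGFbeta, RNA levels were higher for 7 of 25 fibrillar matrix genes, while 1 fell. They were also higher for 4 of 21 contractile genes and 4 of 21 genes for collagen processing and crosslinking. The same held for 4 of 22 genes of the ATF4 pathway and the unfolded protein response. They were lower for 9 of 22 markers of resident fibroblasts, of which 2 rose, for 8 of 26 interferon genes, 4 of 13 complement genes and 4 of 24 cell cycle genes. These 8 were among the 11 lists higher and 4 lower that camera called with a preset correlation. Another was that of canonical TGF-beta targets and feedback genes, which went both ways (4 of 23 rose and 5 fell). With an estimated correlation none of the 8 was called (camera adjusted p = 0.513 to 0.559). With 4 libraries the latter form has little power, so it does not show that correlation between genes made the calls. Nor does it exclude this. Estimated correlations of these 8 lists ran from 0.00562 (resident fibroblast markers) to 0.443 (interferon genes), against the preset 0.01. Wisp1 rose 6.22-fold and Postn, which encodes the matrix protein periostin, 5.79-fold. Acta2, which encodes smooth muscle actin, rose 2.05-fold, while Igfbp4, which encodes a binding protein of insulin-like growth factors, fell from a mean TPM of 2051 to 322. These are levels in libraries that the study describes as HuR-bound RNA and the labels as total RNA, so they are given as levels only. Every limma call was lost when every gene above 0 was tested, and the calls also depended on each vehicle library. That of Acta2 was also lost after quantile normalization (limma adjusted p = 0.0542).

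Wisp1, now Ccn4, encodes a secreted protein of the CCN matricellular family (ENSMUSG00000005124.10, GRCm38 chromosome 15, 66891320 to 66923201, plus strand). Its level was 23.6 ± 2.33 TPM with vehicle and 147 ± 8.26 TPM with TGFbeta (mean ± SD, n = 2 each), and it was higher in 2 of 2 TGFbeta libraries. The log2 change of Wisp1 was 2.59 (SE 0.14, limma adjusted p = 0.00312). The Wisp1 call was lost without vehicle 1 (2.69, limma adjusted p = 0.0828), without vehicle 2 (2.49, limma adjusted p = 0.0924) and when every gene above 0 was tested (2.59, limma adjusted p = 0.0590). Over all settings its adjusted p ranged from 3.48e-05 to 0.0924. Elavl1, which encodes HuR (ENSMUSG00000040028.10, chromosome 8, 4285382 to 4325413, minus strand), had 48.4 ± 3.87 TPM with vehicle and 52.9 ± 2.52 TPM with TGFbeta. Its log2 change of 0.13 (SE 0.14) did not pass the test (limma adjusted p = 0.621).

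**Figure D1:**
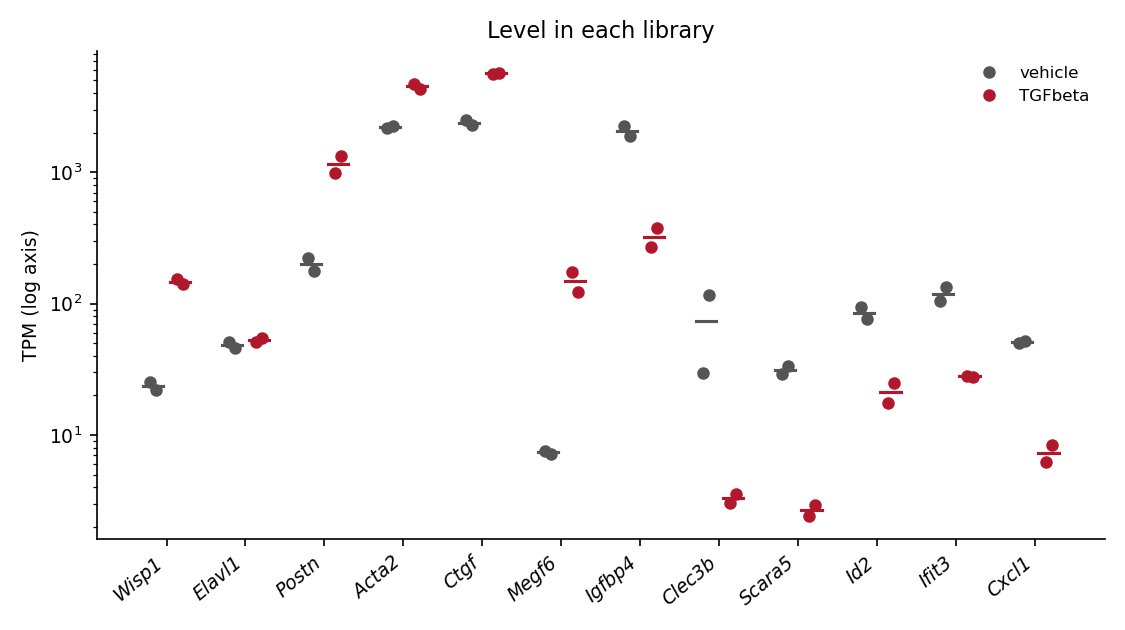
TPM of 12 named genes (log axis), in which each point is 1 library, grey for vehicle and red for TGFbeta, and each horizontal line is a group mean. Wisp1 has group means of 23.6 TPM with vehicle and 147 TPM with TGFbeta, while Elavl1 lies between 45.7 and 54.7 TPM in all 4 libraries.

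The largest increase among named genes was that of Megf6, which encodes a protein with EGF-like domains, from 7.37 to 149 TPM (log2 change 4.14, SE 0.20, limma adjusted p = 0.00312). Fgf21, which encodes an endocrine growth factor, rose by 3.20 and the melatonin receptor gene Mtnr1a by 3.16 on the log2 scale, from vehicle means of 0.455 and 0.4995 TPM. The other genes among the 12 largest increases included Ccl17, Rflnb, Notch4, Acan, Wisp1, Rapgef4, Postn and Kcnj15, with log2 changes from 2.48 to 2.83. The largest decrease among named genes was that of Clec3b, a marker of resident fibroblasts, at -3.82 (SE 0.57, limma adjusted p = 0.0241). It had 29.8 and 117 TPM in the vehicle libraries and 3.05 and 3.53 TPM with TGFbeta. Its log2 change ran from -4.78 to -2.85 over the settings. The solute carrier gene Slc10a6 fell by 3.51, the succinate receptor gene Sucnr1 by 3.39 and the sphingosine-1-phosphate transporter gene Spns2 by 3.37. Selenbp1, Ifitm1, Scara5, Eef1a2, Tnxb, Ptn, Aldh3a1 and Igfbp4 completed the 12 largest decreases, with log2 changes from -3.34 to -2.68.

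In all, limma called 936 genes, 244 higher and 692 lower with TGFbeta, against 3873 genes at an unadjusted p under 0.05. Of the called genes, 177 higher and 415 lower changed at least 2-fold. Separated libraries with a 2-fold change were found for 240 genes higher and 584 lower, 824 together. The other 2 ways of dividing the libraries gave 133 and 146, and limma called 0 genes in each (173 and 270 at an unadjusted p under 0.05). Both of these mix vehicle and TGFbeta libraries within each group. Genes changed by treatment then add to the spread within groups and can hardly separate. These counts may therefore lie below what chance alone would give, and they do not measure false calls. Without a fold limit 55.3% of tested genes were separated, where chance gives 33.3%. The median log2 change of all tested genes was -0.13, and the balance of directions moved with scaling: 350 higher and 410 lower after median scaling, and 333 higher and 401 lower after quantile normalization. No gene was called without vehicle 1 or without vehicle 2 (limma, 0 genes each, with 3033 and 2407 at an unadjusted p under 0.05), while 171 were called without TGFbeta 1 and 203 without TGFbeta 2. This loss without either vehicle library holds for every called gene named here; 21 of the 24 largest genes stayed called without TGFbeta 1 and 21 without TGFbeta 2, the exceptions being Aldh3a1, Clec3b and Tnxb. Every call was also lost when every gene above 0 was tested (limma, 0 genes, 4348 at an unadjusted p under 0.05). Of the 24, Aldh3a1 lost its call with a pseudocount of 5 (-1.62, limma adjusted p = 0.0580), without an intensity trend (0.0522) and in the robust fit (0.0690), and Clec3b in the robust fit (0.109). A pseudocount of 5 brought the log2 changes of genes low in 1 group nearer to 0: Fgf21 had 1.67, Mtnr1a 1.66, Acan 1.51, Rapgef4 1.42, Slc10a6 -1.99 and Sucnr1 -2.14.

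**Figure D2:**
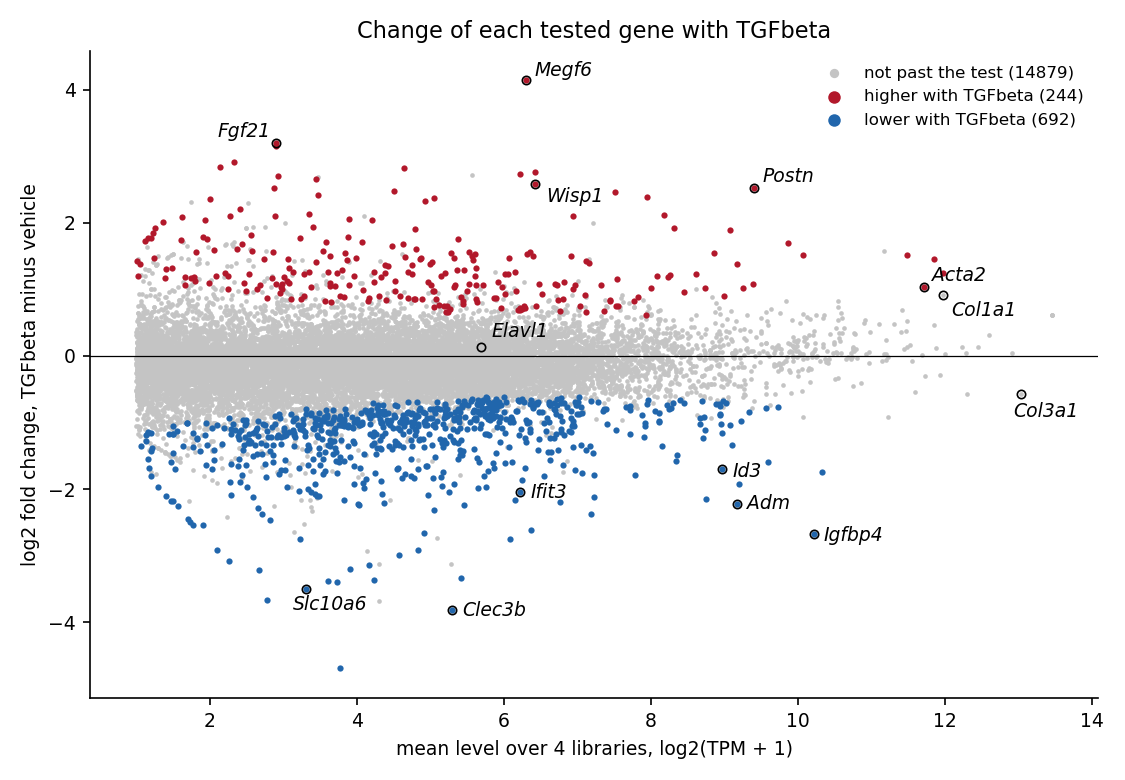
Log2 fold change of TGFbeta over vehicle against mean level (log2(TPM + 1)) for the 15815 tested genes, in which each point is a gene, red for 244 called higher, blue for 692 called lower and grey for those not past the test. Megf6 is the highest labelled gene at 4.14 and Clec3b the lowest at -3.82.

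Of 25 tested genes of the fibrillar matrix, 7 rose, 1 fell and 17 did not pass. Adjusted over the list alone, 13 were higher and 5 lower. Postn rose by 2.52, Cthrc1, which encodes a secreted collagen-associated protein, by 2.46 and Cilp, a gene of cartilage matrix, by 2.37 on the log2 scale, and Eln, which encodes elastin, by 1.52. Col5a3, a minor fibrillar collagen, went the other way and fell by 1.62 (limma adjusted p = 0.00766). The major collagen and fibronectin genes did not pass: Col1a1 had a log2 change of 0.91 (limma adjusted p = 0.0958), Col3a1 of -0.57 (limma adjusted p = 0.172) and Fn1 of 0.02 (limma adjusted p = 0.957). Over the settings Fn1 ran from -0.31 to 0.15, so its sign was not fixed. The median of the list was 0.48 (camera adjusted p = 1.83e-07; adjusted p = 0.513 with an estimated correlation). Of its 8 called members, 4 stayed called without TGFbeta 1, 4 without TGFbeta 2 and 0 without either vehicle library; Col1a1 passed when protein-coding genes alone were tested (limma adjusted p = 0.0299) and with a mean TPM of at least 5 (0.0485).

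Contractile genes showed 4 members of 21 higher, 0 lower and 17 that did not pass; adjusted over the list alone, 8 were higher and 0 lower. Cnn1, which encodes calponin, rose by 1.48 (not past the test without an intensity trend, limma adjusted p = 0.0589), Tagln2 by 1.38, Acta2 by 1.03 and the smooth muscle actin gene Actg2 by 0.89 on the log2 scale. Acta2 went from 2208 ± 68.7 to 4517 ± 301 TPM (mean ± SD, n = 2 each; limma adjusted p = 0.0293), while Tagln had 1583 and 2238 TPM and did not pass (limma adjusted p = 0.137). The list median was 0.19 (camera adjusted p = 2.51e-06; adjusted p = 0.513 with an estimated correlation). That median was 0.28 without vehicle 1, 0.31 without TGFbeta 2, 0.32 after median scaling and 0.29 after quantile normalization. The Acta2 call was lost without TGFbeta 1 (limma adjusted p = 0.0883), without TGFbeta 2 (0.0722) and after quantile normalization (0.76, limma adjusted p = 0.0542), and 1 of the 4 called members stayed called without either TGFbeta library. Among markers of pericytes and smooth muscle 1 of 10 tested rose and 2 fell (2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.474): Mcam rose by 0.98, and Notch3 fell by 1.99 and Steap4 by 2.28, of which 1 stayed called without TGFbeta 1 and 2 without TGFbeta 2.

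Among genes for collagen processing and crosslinking, 4 of 21 rose and 0 fell, all 4 of them in the lysyl oxidase family that crosslinks collagen and elastin; adjusted over the list alone, 7 were higher and 0 lower. Lox rose by 1.70, Loxl4 by 1.20, Loxl3 by 1.06 and Loxl2 by 1.02. The median over all members was 0.27 (camera adjusted p = 0.000154; adjusted p = 0.540 with an estimated correlation). It was 0.17 without TGFbeta 1 and 0.47 without TGFbeta 2. Basement membrane genes were not called as a list (camera adjusted p = 0.628), and their median of -0.06 turned to 0.07 after median scaling. Single libraries moved it, to -0.03 without vehicle 1, -0.23 without vehicle 2, -0.20 without TGFbeta 1 and -0.11 without TGFbeta 2. Within it 4 of 15 fell and 0 rose (1 higher and 5 lower adjusted over the list alone), with Nid2 at -1.41, Col18a1 at -1.08 and Lama4 at -0.82. The Nid2 call was lost after median scaling (limma adjusted p = 0.0541), quantile normalization (0.0602) and without an intensity trend (0.0732), and that of Lama4 without a trend (0.0516) and with the replicate block (0.0504). Of matrix proteases and inhibitors 1 of 19 rose and 2 fell (4 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.943): Plaur, the urokinase receptor gene, rose by 1.68, and Plat, which encodes tissue plasminogen activator, fell by 1.75 and Adamts9 by 1.77. Of the 4 called crosslinking members 0 stayed called without TGFbeta 1 and 1 without TGFbeta 2; of the 4 basement membrane members 0 did without either, and of the 3 protease members 1 did without each.

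Canonical targets and feedback genes of TGF-beta went both ways: 4 of 23 rose, 5 fell and 14 did not pass, or 9 higher and 6 lower adjusted over the list alone. Ltbp2, which encodes a matrix protein related to latent TGF-beta binding proteins, rose by 2.38, Pmepa1 by 1.54 and Ctgf by 1.25. Ctgf reached 5667 ± 43.1 TPM from 2385 ± 141 (mean ± SD, n = 2 each). The 5 that fell were Id2, Id3 and Id1, which encode inhibitors of DNA binding that bone morphogenetic proteins (BMPs) induce, Smad6, an inhibitory Smad, and Smad3, which transmits the TGF-beta signal, with log2 changes of -1.97, -1.69, -1.44, -1.75 and -1.09. Tgfb1 at 0.74 (limma adjusted p = 0.102) and Il11 at 0.88 (limma adjusted p = 0.0727) did not pass. Both did with protein-coding genes alone (limma adjusted p = 0.0409 and 0.0200). Tgfb1 depended on the library, with 0.44 without TGFbeta 1 and 1.04 without TGFbeta 2. Of the canonical targets and feedback genes, Smad7 at -0.40 did not pass (limma adjusted p = 0.161). Their median log2 change was 0.09 (camera adjusted p = 0.0429; adjusted p = 0.683 with an estimated correlation), and that call was also lost without vehicle 1 (0.106), without TGFbeta 1 (0.325), after median scaling (0.135) and quantile normalization (0.204), with every gene above 0 (0.0523), with a mean TPM of at least 5 (0.0861) and with protein-coding genes alone (0.0521). The median was 0.16 without vehicle 1, 0.20 without vehicle 2 and 0.16 without TGFbeta 2, 0.22 after median scaling and 0.21 after quantile normalization. Ctgf lost its call without TGFbeta 1 (limma adjusted p = 0.0609) and without TGFbeta 2 (0.0621), and 6 of the 9 called members stayed called without each TGFbeta library.

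Of the CCN family, 2 of 5 tested members rose, Wisp1 and Ctgf, and 0 fell; the counts were the same adjusted over the list alone. Nov at 0.73 did not pass (limma adjusted p = 0.538) and turned to -0.32 without TGFbeta 2. Its value was also the list median (camera adjusted p = 0.00169; adjusted p = 0.513 with an estimated correlation; 0.0706 after quantile normalization), so the size of that median rested on 1 gene. The median was 1.26 without TGFbeta 1, 0.19 without TGFbeta 2, 0.45 without vehicle 2 and 0.47 with every gene above 0. Targets of YAP and SRF, which respond to cell tension, were not called (camera adjusted p = 0.439; 1 of 19 higher and 1 lower, and the same adjusted over the list alone), and their median of -0.05 turned to 0.09 after median scaling and 0.06 after quantile normalization. It was -0.21 without TGFbeta 1, -0.00498 without TGFbeta 2 and -0.07 without vehicle 2. Ctgf rose and Fhl1 fell by 1.22 (limma adjusted p = 0.0504 without an intensity trend), and of these 2 calls 0 stayed without TGFbeta 1 and 1 without TGFbeta 2.

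Of 22 tested markers of resident fibroblasts, 9 fell, 2 rose and 11 did not pass, or 11 lower and 2 higher adjusted over the list alone. Scara5 fell by 3.14, Pdgfra, the gene of a growth factor receptor that marks fibroblasts, by 1.42, and Tcf21, a transcription factor gene of cardiac fibroblasts, by 1.11 on the log2 scale. Gsn, which encodes the actin-severing protein gelsolin, went from 1999 to 579.7 TPM. The 2 that rose were the homeobox gene Meox1, from 9.10 to 49.7 TPM, and the microfibril gene Mfap4, from 555 to 1596 TPM. The median over all members was -0.52 (camera adjusted p = 0.00169; adjusted p = 0.513 with an estimated correlation). Of its 11 called members, 6 stayed called without TGFbeta 1 and 5 without TGFbeta 2.

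Of 26 interferon response genes 8 fell, 0 rose and 18 did not pass, or 19 lower and 0 higher adjusted over the list alone. Ifit3, an antiviral effector gene, fell by 2.04 (119 ± 21.3 to 27.9 ± 0.136 TPM, mean ± SD, n = 2 each) and Psmb8, an immunoproteasome subunit gene, by 1.85. Oas2 at -1.37 did not pass (limma adjusted p = 0.0794), but did with a mean TPM of at least 5 (0.0352) and protein-coding genes alone (0.0227). Their median log2 change was -0.73 (camera adjusted p = 1.33e-06; adjusted p = 0.559 with an estimated correlation). Beside them, 0 of 14 tested markers of macrophages and leukocytes were called over all genes and 0 adjusted over the list alone by limma (2 at an unadjusted p under 0.05; camera adjusted p = 0.575), with a median of -0.34. That median was -0.50 without vehicle 1, -0.09 without vehicle 2, -0.36 without TGFbeta 1 and -0.13 without TGFbeta 2, and -0.44 and -0.14 with pseudocounts of 0.1 and 5. Lyz2 stood at 60.8 and 45.5 TPM, Cd14 at 3.81 and 1.97 TPM and Cd68 at 13.4 and 9.35 TPM with vehicle and TGFbeta. Ptprc hardly differed, at 1.20 and 1.21 TPM, and C1qb went the other way, at 1.73 and 2.51 TPM. Of the 14 markers, 12 had negative and 2 positive log2 changes. Of the 8 called interferon genes 2 stayed called without each TGFbeta library.

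Complement and acute phase genes showed 4 of 13 lower, 0 higher and 9 not past the test, or 8 lower and 0 higher adjusted over the list alone. C3, the central complement component, fell by 1.24 and the protease gene C1s1 by 0.99, the latter not past the test after median scaling (limma adjusted p = 0.0591), quantile normalization (0.0545) and without an intensity trend (0.0703). C4b at -1.15 did not pass (limma adjusted p = 0.0878) but did without TGFbeta 2 (-1.61, 0.0465), with the replicate block (0.0299), a mean TPM of at least 5 (0.0345) and protein-coding genes alone (0.0219); without TGFbeta 1 it was -0.70 (0.167). The list median was -0.76 (camera adjusted p = 0.00114; adjusted p = 0.513 with an estimated correlation). Inflammatory cytokines and chemokines were not called as a list (camera adjusted p = 0.264): 5 of 23 fell and 1 rose, or 7 lower and 1 higher adjusted over the list alone. The neutrophil chemokine genes Cxcl1 and Cxcl5 fell by 2.66 and 2.61, while Ptgs2, which encodes cyclooxygenase-2, rose by 2.13 from 2.84 to 15.7 TPM. Of called members, 1 of 4 complement genes stayed called without TGFbeta 1 and another 1 without TGFbeta 2 (0 in both fits), and of 6 inflammatory genes 2 without TGFbeta 1 and 3 without TGFbeta 2.

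Of 24 cell cycle genes 4 were lower, 0 higher and 20 did not pass, or 13 lower and 1 higher adjusted over the list alone. The proliferation marker Mki67 fell by 1.14, the spindle checkpoint gene Bub1b by 1.12 and the topoisomerase gene Top2a by 0.95; none of the 4 stayed called without TGFbeta 1 or without TGFbeta 2 (limma, 0 each). The calls were also lost for Bub1b after quantile normalization (limma adjusted p = 0.0560) and for Top2a without an intensity trend (0.0582) and with the replicate block (0.0559). The median over all members was -0.67 (camera adjusted p = 0.000447; adjusted p = 0.540 with an estimated correlation), and -0.41 with a pseudocount of 5. Among p53 targets 2 of 18 rose and 1 fell, or 3 and 1 adjusted over the list alone: Plk2 rose by 1.53 and Gdf15, a stress cytokine gene, by 0.93, and Sesn1 fell by 1.11. Gdf15 did not pass with a pseudocount of 0.1 (limma adjusted p = 0.0523), without an intensity trend (0.0805) or with the replicate block (0.0682). The median of the p53 targets was 0.16 (camera adjusted p = 0.00169; adjusted p = 0.513 with an estimated correlation), rising to 0.29 after median scaling and 0.25 after quantile normalization. Of the 3 called members 1 stayed called without each TGFbeta library. Replication-dependent histone genes were not called (camera adjusted p = 0.710), with 1 of 27 lower, 0 higher and 0 by limma adjusted over the list alone; that member, Hist1h4m, fell by 1.68 from 2.48 to 0.0427 TPM and lost its call after median scaling, quantile normalization, with a pseudocount of 5, without an intensity trend (limma adjusted p = 0.0550, 0.0788, 0.0690 and 0.0504) and without any 1 library.

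Genes of the ATF4 pathway and the unfolded protein response had positive log2 changes in 22 of 22 tested members, of which 4 rose and 18 did not pass. Adjusted over the list alone, 18 were higher and 0 lower. Trib3 rose by 1.5 (limma adjusted p = 0.0610 without an intensity trend), the amino acid transporter gene Slc7a5 by 1.43, Chac1 by 1.38 and Hspa5, which encodes the chaperone BiP, by 0.90 (355 to 666 TPM). Their median log2 change was 0.62 (camera adjusted p = 1.07e-15; adjusted p = 0.513 with an estimated correlation). Of the 4 called members 0 stayed called without TGFbeta 1 and 1 without TGFbeta 2.

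Mitochondrially encoded genes had positive log2 changes in 13 of 13 members with a median of 0.38 (camera adjusted p = 1.69e-05; adjusted p = 0.580 with an estimated correlation). The median was 0.65 without TGFbeta 1 and 0.12 without TGFbeta 2. Limma called 0 of them over all genes and 0 adjusted over the list alone (2 at an unadjusted p under 0.05). The least even was mt-Atp8, with 1870 and 575 TPM with vehicle and 1980 and 4816 TPM with TGFbeta. Cytosolic ribosomal protein genes had a median of 0.05 over 80 members, with 0 called by limma over all genes and 0 adjusted over the list alone (2 at an unadjusted p under 0.05; camera adjusted p = 0.00253; adjusted p = 0.786 with an estimated correlation), and the sign turned after quantile normalization (-0.01) and without TGFbeta 2 (-0.08), with 0.21 without TGFbeta 1 and 0.18 after median scaling. The call was also lost without vehicle 1 (camera adjusted p = 0.0888). Nuclear genes of oxidative phosphorylation were not called (camera adjusted p = 0.747; 1 of 78 higher, 1 lower, and 0 by limma adjusted over the list alone), and their median of -0.06 turned to 0.07 after median scaling and 0.01 after quantile normalization; without TGFbeta 1 the median was 0.05 and the camera adjusted p 0.0118, and without TGFbeta 2 they were -0.17 and 0.0585. Atp5g1 rose by 0.84 and Ndufv3 fell by 0.63, and both calls were lost without any 1 library. The mitochondrial share of TPM was 1.84% and 1.63% with vehicle and 1.98% and 2.87% with TGFbeta.

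Of integrin and adhesion genes 3 of 20 rose and 0 fell, or 6 higher and 2 lower adjusted over the list alone: Cd44, the hyaluronan receptor gene, rose by 1.08, Itga3 by 0.86 and the collagen receptor gene Itga11 by 0.69. The list median was 0.23 (camera adjusted p = 0.00253; adjusted p = 0.646 with an estimated correlation). It fell to 0.07 without vehicle 2 and was 0.36 after median scaling and quantile normalization. Cd44 (limma adjusted p = 0.0583) and Itga3 (0.0651) did not pass without an intensity trend, nor Itga3 with the replicate block (0.0692). Of cartilage, tendon and bone genes 3 of 15 rose and 1 fell, or 4 and 1 adjusted over the list alone. Acan, which encodes the proteoglycan aggrecan, rose by 2.70 from 1.02 to 12.2 TPM, Chst11 by 1.25 and the transcription factor gene Runx1 by 1.23, and Matn2 fell by 0.86. Their median was 0.47 (camera adjusted p = 0.00136; adjusted p = 0.513 with an estimated correlation). It was 0.24 with a pseudocount of 5 and 0.19 with every gene above 0. Of the called members 0 of 3 integrin genes and 1 of 4 cartilage genes stayed called without each TGFbeta library.

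**Figure D3:**
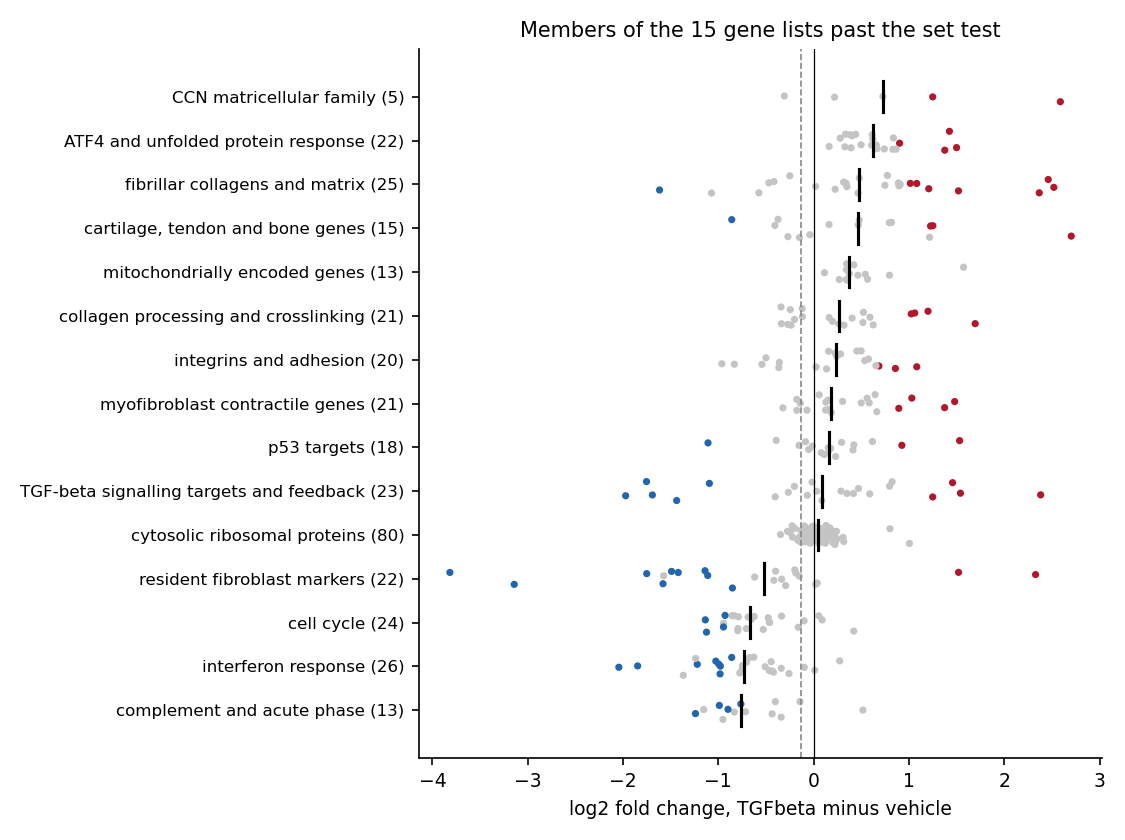
Log2 fold change of TGFbeta over vehicle for the tested members of the 15 lists past the set test with a preset correlation, 0 of which were called with an estimated correlation or by directional fry, in which each point is a gene, red or blue where called higher or lower and grey otherwise, each black bar a list median and the dashed line the median of all tested genes (-0.13). All 22 members of the ATF4 and unfolded protein response list lie above 0, with a median of 0.62. The interferon list has a median of -0.73. The ribosomal median of 0.05 turned negative after quantile normalization (-0.01).

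Secreted growth factors and cytokines of fibrosis were not called as a list (camera adjusted p = 0.0520), but were with a pseudocount of 5 (0.0475) and without an intensity trend (0.0412). Of 24 tested, 4 rose and 2 fell, or 7 and 5 adjusted over the list alone: Igf1 rose by 1.57 and Lif by 1.53, and Bmp4 fell by 1.79. Immediate early genes showed 4 of 19 higher and 2 lower, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.109), with Egr2 up by 1.61, Myc by 1.06 and Fosl1 by 0.86 (limma adjusted p = 0.0882 with the replicate block); the camera adjusted p was 0.0147 without TGFbeta 2, and the median of 0.06 was -0.07 without TGFbeta 1, 0.14 without TGFbeta 2, 0.04 without vehicle 1, 0.20 after median scaling and 0.21 after quantile normalization. In the Wnt pathway 1 of 24 rose and 4 fell, or 1 and 7 adjusted over the list alone (camera adjusted p = 0.806). Sfrp2, a secreted Wnt modulator gene, fell by 2.37 and the Wnt inhibitor gene Apcdd1 by 1.18, while Nkd2 rose by 1.11; the list's median of 0.01 and mean of -0.12 differed in sign, and the median was negative without vehicle 2 (-0.07) and TGFbeta 2 (-0.20), with 0.04 without vehicle 1, 0.05 without TGFbeta 1, 0.15 after median scaling and 0.13 after quantile normalization. Of called members, 4 of 6 secreted factors, 0 of 6 immediate early genes and 1 of 5 Wnt genes stayed called without each TGFbeta library.

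Messages that HuR is known to bind were not called as a list (camera adjusted p = 0.114): 3 of 28 rose, 2 fell and 23 did not pass, or 3 and 3 adjusted over the list alone. Ptgs2 rose by 2.13, Plaur by 1.68 and Myc by 1.06, and the cyclin gene Ccnd1 fell by 1.70 and Dusp1 by 0.65. Their median of 0.03 was -0.04 without vehicle 2, 0.05 without vehicle 1 and 0.08 without TGFbeta 2, and 0.16 after median scaling and 0.10 after quantile normalization. With a mean TPM of at least 5 it was 0.10 and the camera adjusted p was 0.0438. Of these 5 called members, 0 stayed called without TGFbeta 1 and 1 without TGFbeta 2. Of the RNA-binding proteins of AU-rich elements 2 of 19 fell and 0 rose, or 2 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.979), and the median of -0.09 turned to 0.04 after median scaling and 0.02 after quantile normalization, with -0.17 without TGFbeta 1 and -0.14 without vehicle 2. Zfp36l2, which encodes a protein that promotes decay of such messages, fell by 1.65 and Celf2 by 0.76, the latter not past the test after median scaling, quantile normalization, without an intensity trend, with the replicate block (limma adjusted p = 0.0588, 0.0542, 0.0702 and 0.0626) or without any 1 library. Of these 2, 1 stayed called without each TGFbeta library.

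Among metabolic lists, limma called 0 of 19 cholesterol and fatty acid genes over all genes and 0 adjusted over the list alone (2 at an unadjusted p under 0.05; camera adjusted p = 0.109; 0.0326 without vehicle 2), with Cyp51 at 0.50 (past the test with protein-coding genes alone, limma adjusted p = 0.0496). Of glycolysis and hypoxia genes 1 of 19 fell and 0 rose, or 2 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.806), and the median of -0.11 turned to 0.02 after median scaling, with -0.17 without vehicle 1 and -0.05 without vehicle 2. That member was Adm, the gene of the vasodilator peptide adrenomedullin, which fell by 2.23 from 949 to 199 TPM and stayed called without each TGFbeta library. Of antioxidant genes 1 of 18 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.575); Gstm1 fell by 1.93 from 944 to 226 TPM and lost its call without any 1 library, after median scaling and quantile normalization, without an intensity trend and in the robust fit (limma adjusted p = 0.0607, 0.0536, 0.0670 and 0.103).

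Of adipocyte markers 1 of 6 fell and 0 rose, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.0613). The list was called without vehicle 1 (0.0314), without TGFbeta 2 (0.0188), after median scaling (0.0340) and quantile normalization (0.0431), without an intensity trend (0.0431), with the replicate block (0.0398) and with protein-coding genes alone (0.0409). Its member Lpl, which encodes lipoprotein lipase, fell by 1.19, a call lost without TGFbeta 1. Of endothelial markers 1 of 13 rose and 0 fell, or 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.907); Erg, a transcription factor gene, went from 2.00 to 7.88 TPM, a call lost without any 1 library, while Cldn5 stood at 3.10 and 1.45 TPM. Limma called 0 of 9 cardiomyocyte markers over all genes and 0 adjusted over the list alone (2 at an unadjusted p under 0.05; camera adjusted p = 0.628), and Tnnt2 stood at 64.2 and 34.9 TPM (limma adjusted p = 0.125). Lists with fewer than 5 tested members were not tested as lists, and limma called none of their members: 0 of 4 mesothelial, 0 of 4 Schwann and neural, 0 of 1 red cell and 0 of 4 sex-linked genes (1, 1, 0 and 0 at an unadjusted p under 0.05), with Upk3b at 10.7 and 7.04 TPM and Alas2 at 8.79 and 10.8 TPM. The lists of small nucleolar and microRNA genes and of nuclear noncoding RNAs had 0 tested members. In all, camera called 11 lists higher and 4 lower of 34; with an estimated correlation it called 0 (smallest adjusted p = 0.513) and directional fry called 0 (smallest adjusted p = 0.0936), while fry in either direction called 27. Among lists not called, camera placed some above other genes against the sign of their mean or median: the Wnt list (mean -0.12), the RNA-binding proteins (median -0.09, mean -0.13), the YAP and SRF targets (median -0.05), the pericyte markers (median 0.12, mean -0.16) and the nuclear oxidative genes (median -0.06, mean -0.08), of which the medians of the RNA-binding proteins, YAP and SRF targets and oxidative genes turned positive after median scaling. The pericyte median was 0.05 without vehicle 2, 0.04 without TGFbeta 1 and 0.01 without TGFbeta 2, and 0.25 after median scaling and 0.23 after quantile normalization.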

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

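The alternative of protein-coding genes without identical twins, which also rescaled each library, was chosen after the data were seen. Wisp1 stayed past the threshold in 12 of 15 settings, with log2 changes of 2.41 to 2.72; when every gene above 0 was tested limma called 0 genes higher and 0 lower (4348 at an unadjusted p under 0.05), and Wisp1 at 2.59 had an adjusted p of 0.0590, where more genes were tested and the low ones entered the trend. Elavl1 did not pass in any setting (0.05 to 0.26). Without 1 library, genes called higher numbered 0 to 65 and lower 0 to 138, where fewer samples were used, separated genes with a 2-fold change 270 to 374 higher and 621 to 793 lower, and Wisp1 had 2.49 to 2.69. Genes called lower numbered 401 after quantile normalization and 410 after median scaling, which centre the libraries, 437 without an intensity trend, and 1203 lower and 482 higher for protein-coding genes; the causes of the last 2 changes were not tested. With the replicate number as a block 445 were lower. Deviations of same-numbered libraries from their group means correlated at -0.0539 across genes, so no shared effect of the number was seen. With 2 pairs this cannot settle whether the samples were paired. Separated genes numbered 879 lower with a pseudocount of 0.1, 112 higher and 249 lower with 5, which shrinks ratios of low genes, and 376 lower after quantile normalization. Lists called numbered 0 higher and 0 lower with an estimated correlation, and 0 and 0 with fry. The former relies on few degrees of freedom and, for some lists, on a correlation well above the preset. The ribosomal median reversed to -0.00615 after quantile normalization, the cause not tested, and ranged from -0.0834 to 0.213 without 1 library. Of the named genes' values 1169 kept direction and side of the threshold, 122 lost the call, 38 gained it, 3 uncalled ones changed sign and 0 called ones did; without 1 library these were 282, 250, 2, 6 and 0. Of the list medians these were 215, 6, 5, 9 and 1, and without 1 library 123, 3, 4, 5 and 1. Depth was unknown, so its limit on low genes could not be given.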

Other observations

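The lists in this paragraph and the next were chosen after the called genes were seen, so their counts describe and are not independent evidence. Genes of BMP signalling were lower with TGFbeta in 11 of 23 tested members, 0 were higher and 12 did not pass (12 lower and 0 higher adjusted over the list alone; camera adjusted p over the 5 such lists = 6.34e-05; adjusted p = 0.247 with an estimated correlation). They included the ligand gene Bmp4 (-1.79), the target genes Id1, Id2, Id3 and Id4 (-1.44, -1.97, -1.69 and -1.16), Atoh8 (-1.45) and the extracellular modulators Chrdl1 (-1.63) and Kcp (-1.60). Receptors and ligands of the cAMP and cGMP pathways were lower in 9 of 18 and higher in 0, or 10 and 0 adjusted over the list alone. As a list they had a camera adjusted p of 6.34e-05, and of 0.241 with an estimated correlation. Adm fell by 2.23, the adenosine receptor genes Adora2a and Adora2b by 2.22 and 1.49, the natriuretic peptide receptor gene Npr1 by 1.90 and the prostacyclin receptor gene Ptgir by 1.44. Of called members, 7 of 11 BMP genes and 1 of 9 receptor genes stayed called without each TGFbeta library, and 0 of either list without each vehicle library.

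Enzymes of drug and aldehyde metabolism were lower in 19 of 48 and higher in 1 (30 lower and 3 higher adjusted over the list alone; camera adjusted p = 1.77e-08; adjusted p = 0.247 with an estimated correlation), with Aldh3a1 at -2.75, Fmo2 at -2.04 and Gstt1 at -1.81, while Gsto1 rose by 1.48. Genes of amino acid and one-carbon metabolism were higher in 6 of 21 and lower in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 6.17e-10; adjusted p = 0.247 with an estimated correlation). Bcat1 rose by 1.51, the folate enzyme gene Mthfd2 by 1.08 and the proline synthesis gene Pycr1 by 1.03, while the glutamine transporter gene Slc1a5 fell by 1.04. Notch pathway genes went both ways and were not called as a list (camera adjusted p = 0.117): Notch4, Dner and Heyl rose by 2.73, 2.10 and 1.60, and Notch3, Dtx4 and Jag1 fell by 1.99, 1.98 and 1.14, within 3 higher and 5 lower of 22 (3 and 6 adjusted over the list alone). Of called members without TGFbeta 1 and without TGFbeta 2, 1 and 4 of 20 enzymes, 1 and 1 of 7 amino acid genes and 2 and 4 of 8 Notch genes stayed called, and 0 without either vehicle library.

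Both tests on the interferon genes were chosen after the result was seen, and the test that left out abundant genes was added after the result of median scaling was seen; the GC and motif tests and median scaling were set before. Of 936 called genes 26.1% were higher with TGFbeta. A trend of each library on transcript GC content and length was tested as the whole cause. After its removal, over the 15567 genes with both measures, 26.7% of 1744 called genes were higher. The rank correlation of change with GC went from -0.204 to -0.00711. This argues against the slope of the trend as the whole cause. The removal kept the median of each library's fitted trend, and so any shift common to its genes. Whether GC or length caused such a shift could not be decided this way and stays open. Library composition cannot be told apart from a true excess of lower genes: after median scaling 46.1% of called genes were higher, above the 45% set in advance, but centring moves this share by construction, and for that reason the value was not counted as deciding after it had been seen. Rescaling without the 100 most abundant genes gave 38.8% of 791 (binomial SE 1.73). This lies under the bound of 40% set in advance by less than that SE. The SE treats the called genes as independent and does not measure the spread between libraries. The need to pass that bound by more than the spread was stated after this value was seen. This explanation therefore also stays open, as does an effect of TGFbeta on RNA levels.

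Interferon response genes had a mean log2 change of -0.75. Fewer leukocytes in the TGFbeta cultures were argued against as the whole cause, though only weakly. The mean change of 14 leukocyte markers, 0 of them in another list, was -0.27. It lay 0.484 above that of the interferon genes (SE 0.130). As 11 of the markers had a mean TPM under 5, the difference was also taken with pseudocounts of 0.1 (0.463, SE 0.157) and 5 (0.453, SE 0.0955). Over the 3 markers and 23 interferon genes at or above 5 TPM it was 0.534 (SE 0.193). The difference exceeded 2 SE each time. Each SE rests on 2 libraries per group and is itself poorly known, so 2 SE is a lenient bound. Library composition, as 1 factor per library, was also argued against only weakly as the whole cause. The interferon median of -0.73 was -0.60 after median scaling (camera adjusted p = 2.65e-07) and -0.56 after quantile normalization (2.85e-07); over all alternatives with the preset correlation the adjusted p was 1.00e-08 to 0.000257, and with an estimated correlation it was 0.559. With every library centred on the median of all tested genes the change was -0.582 (SE 0.208 between libraries), 2.31 SE below the -0.1 that such a factor would allow. That bound was chosen after the values were seen, in place of an earlier -0.3 that the change passed by 1.35 SE, so the margin is small. This SE too rests on 2 libraries per group. A response of the fibroblasts to TGFbeta may account for the pattern, as a hypothesis found and tested on the same data; other technical causes were not tested.

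If levels in these libraries followed HuR binding that changed with TGFbeta, change might rise with the density of HuR-like motifs in the 3' UTR. Across 13346 genes, which are not independent replicates, the rank correlation of log2 change with U-rich heptamers was 0.140, and 0.0102 given 3' UTR GC, 3' UTR length and mean level (permutation p = 0.234, adjusted p = 0.234 over 2 motifs). For the pentamer AUUUA it was 0.141, and 0.0162 given the same measures (permutation p = 0.0594, adjusted p = 0.119). Both lie under the bound of 0.05 set in advance, which argues against a relation beyond base composition. Base content itself was related to change (rank correlation with 3' UTR GC -0.192) and is bound up with U content, so a relation through it stays open.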
